A study of Mus musculus with 7 samples.

How the data were processed

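Messenger RNA was measured in livers of newborn male C57BL/6J mice on day of life 1, with 1 Affymetrix Mouse Genome 430 2.0 array per liver. There were 3 wild type and 4 glycerol kinase knockout livers. Per the labels' protocols, RNA was extracted from each liver separately, so arrays stand for separate animals, and the wild type mice were littermates of knockout mice. Litters, array batches and scan dates were not used here. Groups and replicate numbers come from the sample titles.

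The values are intensities on a linear scale, 1 per probe set and array, as deposited by the submitters. The software GCOS is named, without a version, per the submitters' processing notes, and the method that summarises probes into probe sets is not given in the sources used here. In the deposited intensities, the mean of each array after its lowest and highest 2% of probe sets were left out was 500.003, so every array had been scaled to 1 common target. Such scaling makes arrays comparable on average and cannot show a change of total messenger RNA. Median intensities ran from 92.7 to 108.3, and between 35.4% and 39.4% of the probe sets of an array lay under an intensity of 50, where noise weighs most. The number of arrays limits the precision of every comparison.

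Intensities were transformed to log2(value + 16). The array medians on that scale lay between 6.76 and 6.96, within the limit of 0.2 set for using the values as deposited, so no further scaling was applied. After 64 control probe sets were left out of 45101, probe sets with a mean above the median of all were kept, which left 22518. Each was compared between knockout and wild type with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), without covariates, and called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(intensity + 16) scale, which understates changes of dim probe sets. Errors of fold changes are standard errors from limma, and errors of intensities are SDs over 3 wild type or 4 knockout arrays. Plots were drawn with matplotlib 3.10.9.

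Probe sets were named from the platform annotation given with the values. It gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and no gene was named from a probe set with several. Of the probe sets with 1 symbol, 34754 were found by gene ID in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. That table served only for names and for which genes neighbour each other. The transcript of the targeted gene is not reported here, so the knockout labels were not checked by it.

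Before the data were examined, 32 lists with 549 genes were fixed, covering metabolic pathways, stress and hormone responses, and markers of cell types that a newborn liver can hold. Of these genes 507 had a named probe set and 467 were tested. Lists with at least 5 measured genes, 31 in all, were tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each gene, with adjustment over lists. Camera asks whether a list moved relative to the other genes. Camera with an estimated correlation and fry were run beside it. Counts of members were also adjusted over the list alone. The mean log2 level of a list in each array, its score, was compared with an exact two-sided permutation test over the 35 splits of 7 arrays into 3 and 4, whose smallest p is 0.0286; this test was added after the lists had been seen.

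Coexpression modules were built without group labels from the 4000 kept probe sets of largest SD, with |r| to the power 6, topological overlap, average linkage and 25 clusters, of which those with at least 30 probe sets were modules. Genes within 5 Mb of the targeted gene were set against 10000 random lists matched on mean expression. The text names, per direction, the 12 genes with the largest change among called probe sets whose groups did not overlap, up to 4 members of smallest p in each list past its threshold, and up to 2 in other lists. Genes named outside this rule were chosen after their values were seen.

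The steps were tested on simulated data for the comparison of knockout with wild type over 22518 probe sets, with 50 probe sets changed at each fold. The test recovered 6% of those changed 1.5-fold, 36% at 2-fold, 92% at 4-fold and 96% at 8-fold, and 4.96% of its calls were unchanged probe sets. Small changes were mostly missed in that setting. The simulated noise was independent between probe sets and only 200 were changed, so these rates need not hold for the real arrays. Alternatives fixed before the data were examined covered the offset, the scaling between arrays, the filter, the variance model, each array left out in turn, replicate numbers as a block, the threshold, shared probe sets, the list test, the network settings and the window around the targeted gene.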

Results

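Liver transcripts were profiled on day of life 1 in 3 wild type and 4 glycerol kinase knockout male mice, 1 array per liver. Glycerol kinase converts glycerol to glycerol 3-phosphate. The age was chosen by the submitters because knockout pups do not yet show signs of the deficiency, so the comparison addresses transcript changes that precede overt disease. Arrays correlated with each other at r between 0.930 and 0.985 over tested probe sets, and no pair held identical values. The first principal component carried 37.8% of the variance and separated the groups (exact permutation p = 0.0286, two-sided, the smallest that 35 splits allow). No 3' to 5' control ratio separated the groups (exact permutation p from 0.486 to 1), although knockout 3 had the highest of the 7 arrays for every control. Its transferrin receptor ratio was 11.1 against 7.22 to 7.32 in the other knockout arrays. Against all other arrays, its actin ratio was 1.45 against 1.12 to 1.35. Its Gapdh ratio was 1.07 against 0.90 to 0.96, and its pyruvate carboxylase ratio 7.28 against 3.46 to 6.39. The 3' probe set of the cre control was lower in every knockout array, at 20509 to 23577 against 23689 to 25428 (exact permutation p = 0.0571), and that of the bioB control overlapped between groups (exact permutation p = 0.429).

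**Figure D1:**
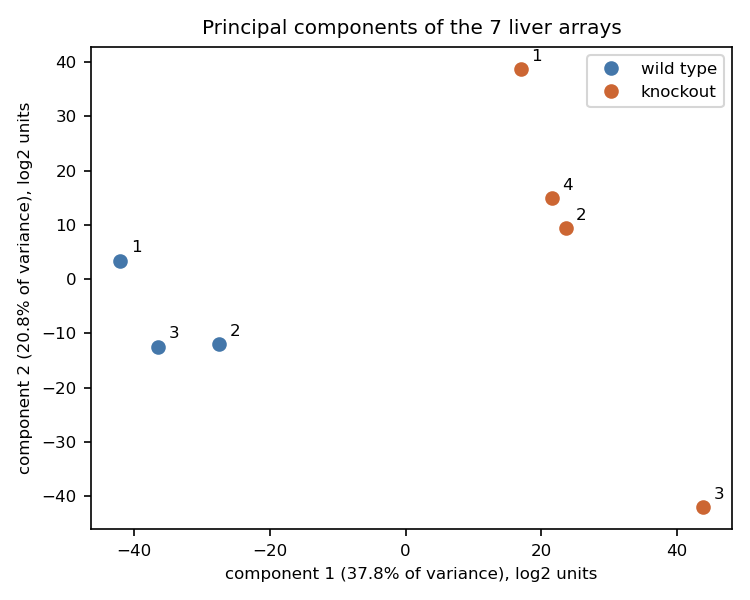
Principal components 1 and 2 of the 7 arrays, in log2 units, with replicate numbers beside the points. Wild type arrays lie between -42.07 and -27.47 on component 1 and knockout arrays between 17.04 and 43.86.

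Transcripts of Gpd1 and Acaa1b were among those higher in knockout liver. Gpd1, the cytosolic glycerol 3-phosphate dehydrogenase, rose from an intensity of 337.1 ± 51.0 to 2500 ± 549 (SD, n = 3 and 4). Acaa1b, a peroxisomal thiolase, rose from 1998 ± 665 to 15484 ± 2945. The organic anion transporter Slco4c1 fell from 1433 ± 826 to 83.6 ± 31.9. In all, 955 of 22518 probe sets passed limma's adjusted p of 0.05, 529 higher and 426 lower in knockout, and they covered 729 named genes, with 89 probe sets not named. A change of at least 2-fold was seen in 365 of them, 240 higher and 125 lower. Of the called probe sets 55.4% were higher, or 71.2% of 756 when arrays were scaled to equal medians. The groups did not overlap in 21.1% of tested probe sets, against 5.71% by chance. The count depended on which array was left out. It was 341 without wild type 1, 288 without wild type 2, 127 without wild type 3, 514 without knockout 2 and 375 without knockout 4. Without knockout 1 it was 1006 and without knockout 3 it was 930. Fewer arrays also give less power.

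Among the 12 largest rises, Cyp1a2, a cytochrome P450 of drug metabolism, had a log2 fold change of 3.35 ± 0.59 (adjusted p = 0.0172) and Acaa1b one of 2.99 ± 0.23 (adjusted p = 0.00075). Crot, the peroxisomal carnitine octanoyltransferase, rose by 2.66 ± 0.28 on the log2 scale. The acyl-CoA thioesterases Acot3 and Acot4 rose by 2.84 ± 0.31 and 2.34 ± 0.24, and Gpd1 by 2.82 ± 0.19 (adjusted p = 0.00056), with its 2 other probe sets in the same direction. The fatty acid hydroxylase Cyp4a12a rose by 2.30 ± 0.32, the junction protein gene Igsf5 by 2.29 ± 0.25 and Smlr1 by 2.65 ± 0.27. The rest were Mettl7b at 2.92 ± 0.62, G0s2, an inhibitor of triglyceride lipase, at 2.70 ± 0.48, and Smcp at 2.60 ± 0.58. Acaa1b, Acot3, Gpd1, Crot, Smlr1, Acot4, Cyp4a12a and Igsf5 passed whichever array was left out. Leaving out 1 array moved the log2 fold change of Cyp1a2 to 2.73 (without wild type 1), of Mettl7b to 2.23 (without knockout 3) and of Smcp to 1.85 (without wild type 1). Cyp1a2 did not pass without wild type 1 or 3 (highest adjusted p = 0.0534) nor G0s2 without wild type 2 or 3 (0.0822), Mettl7b failed without any wild type array or knockout 2 or 4 (0.120), and Smcp without wild type 1 or 3 or knockout 2, 3 or 4 (0.115).

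Among the 12 largest falls, Slco4c1 had a log2 fold change of -3.76 ± 0.38 (adjusted p = 0.0020), a 13.6-fold lower level. Genes are ranked here by their probe set of smallest p, and another called probe set of Fam107a was lower still, at -4.74 ± 0.64. The ranked one of Fam107a was at -3.62 ± 0.46, the sulfotransferase Sult3a1 at -3.55 ± 0.83 and Rasd2, a small GTPase, at -3.28 ± 0.41. Esrrg, an orphan nuclear receptor related to the estrogen receptors, fell by 2.73 ± 0.39 on the log2 scale. Trgv4, a variable segment of the T cell receptor gamma chain, fell by 2.46 ± 0.24, and Itgae, an integrin subunit of T cells in epithelia, was at -1.99 ± 0.34. The others were Gm19439 at -2.83 ± 0.56, Minar1 at -2.34 ± 0.31, Gdf3 at -2.24 ± 0.37, Plek2 at -2.07 ± 0.26 and the kinase Map3k6 at -2.06 ± 0.28. Slco4c1, Esrrg, Plek2 and Map3k6 passed whichever array was left out. Fam107a, Rasd2 and Trgv4 passed in the 4 of 7 such runs that tested them, and Minar1 in 5. In the other runs, all without a wild type array, they fell below the expression filter. Their dependence on single wild type arrays was thus untested for Fam107a, Rasd2 and Trgv4 and mostly untested for Minar1. The wild type intensities of Sult3a1 ran from 156.4 to 3071.3, and its log2 fold change was -4.69 without wild type 1 and -2.61 without wild type 3. Sult3a1 did not pass without wild type 2 or 3 or knockout 2, 3 or 4 (highest adjusted p = 0.161), Gm19439 without any wild type array or knockout 4 (0.122), Gdf3 without wild type 1 or 2 (0.0536) and Itgae without wild type 3 (0.0811).

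**Figure D2:**
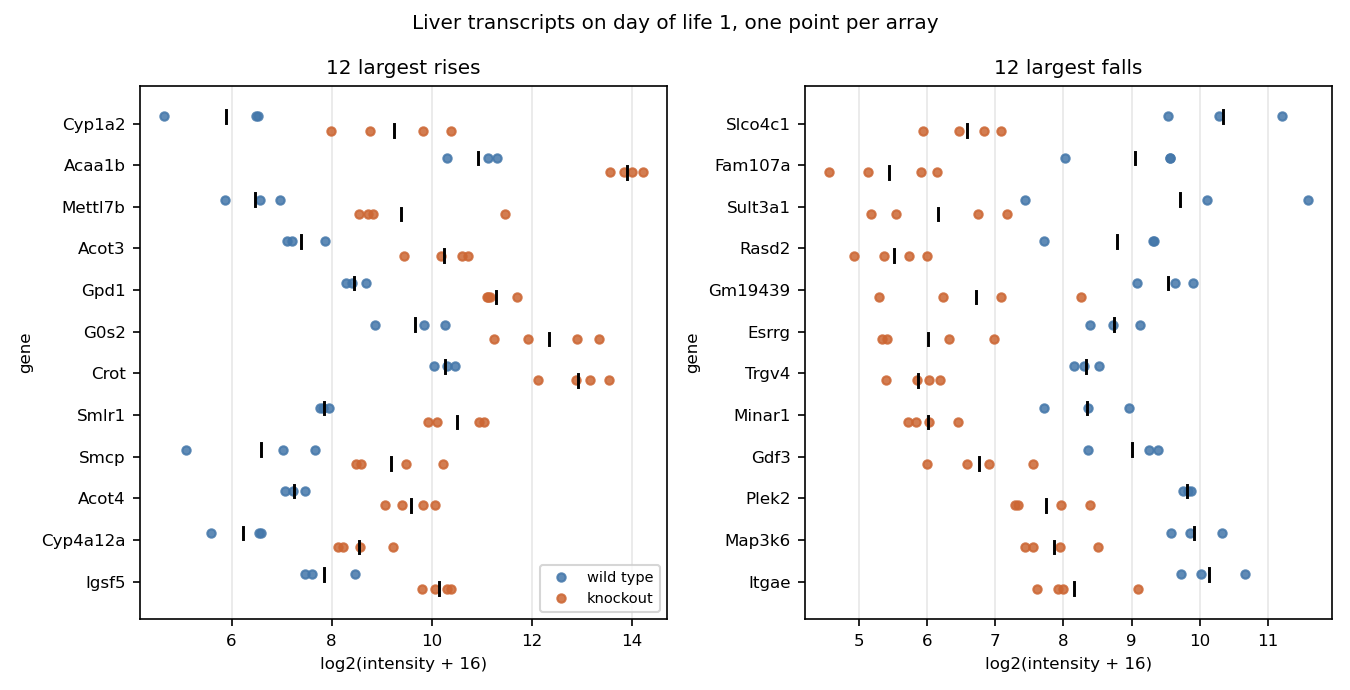
Log2(intensity + 16) of the 12 largest rises and the 12 largest falls, 1 point per array, with black bars at group means. By the rule that chose these genes, the 3 wild type and 4 knockout arrays do not overlap in any of them. The log2 fold change of Gpd1 is 2.82.

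Fatty acid oxidation genes were higher in knockout, and their list had the smallest camera p of the 31. By the brightest probe set of each gene, all 22 measured genes of oxidation and ketogenesis were higher in knockout, also under both other scalings and without any 1 array, 13 of them past the threshold and 20 when adjusted over the list alone, and the median log2 fold change was 0.79. Besides Acaa1b, the bifunctional peroxisomal enzyme Ehhadh rose by 1.82 ± 0.20, Hsd17b4 of the same peroxisomal pathway by 1.27 ± 0.15 and Cpt2, the inner mitochondrial carnitine palmitoyltransferase, by 2.14 ± 0.26. Each of these genes passed whichever array was left out. Cpt1a, its partner at the outer mitochondrial membrane, was at 0.33 (adjusted p = 0.55) and did not pass, and its 2 other probe sets were at -0.22 and 0.05, the only opposite sign among 14 other tested probe sets of the list. Limma's camera gave an adjusted p of 6.7e-16 for the list, but the adjusted p = 0.194 with an estimated correlation, and the list score differed with an exact permutation p of 0.0286.

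Genes of the fixed list for targets of PPAR alpha, a nuclear receptor activated by fatty acids, moved unevenly. Acaa1b, Ehhadh, Cpt2 and Hsd17b4 were counted in the oxidation list and not here, so the counts cover this list only. Of 16 measured genes 6 rose and 0 fell, or 7 and 1 when adjusted over the list alone. Acot1 rose by 2.02 ± 0.21 and Cyp4a31 by 1.69 ± 0.23, next to Acot3 and Acot4, and these 4 genes passed whichever array was left out. Pdk4 at -0.26, Angptl4 at 0.17 and Cd36 at -0.48, also known targets, did not pass, and 1 other tested probe set of Angptl4 had the opposite sign. The Acot genes named here are similar neighbours on chromosome 12, and the probe set of Acot3 is of a type shared between transcripts, so their signals may not be separate. The list had an adjusted p of 0.0015 with camera (adjusted p = 0.538 with an estimated correlation) and an exact permutation p of 0.0286 for its score.

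Of 19 measured glycerol and triglyceride genes 14 were higher in knockout, 7 of them past the threshold, and 5 were lower, 0 of them past it. Without 1 array 11 to 15 were higher. Adjusted over the list alone, 9 rose and 1 fell. The list's brightest Gpd1 probe set rose by 2.57 ± 0.20. Dgat2, which makes triglyceride from diglyceride, rose by 0.89 ± 0.13, Mttp, which loads lipid onto lipoproteins, by 1.02 ± 0.16, and Plin2, a coat protein of lipid droplets, by 1.55 ± 0.27. The list had a median of 0.83, an adjusted p of 0.00033 with camera and an exact permutation p of 0.0286 for its score. The adjusted p = 0.242 with an estimated correlation. Dgat2 and Mttp did not pass without wild type 3 (adjusted p = 0.0501 and 0.0673), nor Plin2 without wild type 1 or 3 (highest 0.0815).

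Genes of the p53 and apoptosis list were mostly lower in knockout, 5 past the threshold against 2 that rose, of 18 measured. Adjusted over the list alone, 11 fell and 2 rose. Trp53inp1, a stress-induced partner of p53, fell by 1.86 ± 0.31, the growth arrest gene Gadd45a by 1.26 ± 0.21 and the antiproliferative gene Btg2 by 1.13 ± 0.16. The 2 that rose were Fas, the death receptor, at 1.91 ± 0.39, and Cideb, from an intensity of 2398 ± 929 to 6441 ± 692. Cideb is known for lipid droplets and lipoprotein assembly as well as for cell death. Camera gave an adjusted p of 0.00015 (adjusted p = 0.194 with an estimated correlation), and the exact permutation p of the score was 0.0286. Btg2 and Cideb passed whichever array was left out. Trp53inp1 did not pass without wild type 3 (adjusted p = 0.0805) nor Gadd45a without wild type 2 or 3 (highest 0.0714), and Fas failed without any wild type array or knockout 2 or 4 (highest 0.108).

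Cell cycle genes leaned lower in knockout, few of them past the threshold. By the brightest probe set of each gene, all 26 measured genes were lower, or 25 under median scaling or without wild type 1 or knockout 1. The median log2 fold change was -0.38, but only Rrm2, a subunit of ribonucleotide reductase, at -0.73 ± 0.17, and Cdca8, at -0.54 ± 0.13, passed. Adjusted over the list alone, 9 fell. The camera adjusted p was 2.6e-08 (adjusted p = 0.538 with an estimated correlation), and the exact permutation p of the score was 0.0286. Erythroid genes, which mark red cell precursors in newborn liver, leaned the same way. Of 19 measured erythroid genes 18 were lower, with a median of -0.39, and Slc4a1 at -0.39 ± 0.09, Rhag at -0.49 ± 0.11 and Trim10 at -0.68 ± 0.16 fell, or 9 genes when adjusted over the list alone. That list had a camera adjusted p of 1.8e-06 (adjusted p = 0.466 with an estimated correlation) and an exact permutation p of 0.0571. These single-gene calls were marginal: Rrm2 failed without any wild type array or knockout 2 (highest adjusted p = 0.156) and Slc4a1 without any wild type array or knockout 1 or 4 (0.189). Among runs without 1 array, Cdca8 and Rhag passed only without knockout 3 (highest 0.184 and 0.182) and Trim10 only without knockout 1 (0.189). Rrm2, Cdca8, Slc4a1, Rhag and Trim10 also lost their calls under median scaling, and Slc4a1 under quantile normalization too.

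The lists of oxidative phosphorylation, bile acid metabolism and the unfolded protein response passed upward with camera, on few genes past the threshold. By the brightest probe set of each gene, all 23 measured respiratory chain genes were higher, with a median of 0.29, but 19 were without knockout 3, 20 without wild type 1 and 22 without wild type 3 or knockout 4. The list's mean of 0.26 became 0.15 without knockout 3. Of the 13 genes with other tested probe sets, 5 had at least 1 that was lower in knockout, namely Atp5a1, Atp5o, Cox5a, Cox6c and Sdha. Only Cox5a passed, at 0.50 ± 0.10, with the same count adjusted over the list alone, and its 2 other probe sets were at -0.07 and -0.09. The list's camera adjusted p was 6.0e-05 (adjusted p = 0.538 with an estimated correlation) and its exact permutation p 0.0571. Of 13 bile acid genes 5 rose and 0 fell, or 6 and 1 when adjusted over the list alone. The uptake transporter Slco1b2 rose by 1.54 ± 0.30, the bile acid receptor Nr1h4 by 1.08 ± 0.23 and the conjugating enzyme Baat by 0.93 ± 0.20, whereas Cyp7a1, the first enzyme of bile acid synthesis, was at 0.25 and did not pass. The list's mean of 0.46 became 0.31 without wild type 1. The camera adjusted p was 0.0059 (adjusted p = 0.538 with an estimated correlation) and the exact permutation p 0.114. Of 15 genes of the unfolded protein response 14 were higher by the brightest probe set, although 8 of 20 other tested probe sets of its members had the opposite sign. Sel1l rose by 0.88 ± 0.16, and 3 rose when adjusted over the list alone. Its camera adjusted p of 0.0059 became 0.0596 without knockout 3 (adjusted p = 0.538 with an estimated correlation, exact permutation p = 0.0571). Slco1b2 did not pass without knockout 2 or 4 (highest adjusted p = 0.0666), Nr1h4 without wild type 1 or 3 or knockout 2 or 4 (0.108), Baat without any array but knockout 1 (0.152), and Cox5a and Sel1l without any wild type array or knockout 4 (0.157 and 0.106).

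The lists of genes that respond to glucocorticoids, to amino acid shortage through ATF4 and to hypoxia passed downward with camera, on few genes past the threshold. Of 16 glucocorticoid response genes 3 fell and 1 rose, or 4 and 1 when adjusted over the list alone. Among these falls was Gadd45a, which the p53 list counted too. The kinase gene Sgk1 fell by 1.27 ± 0.29 and Zbtb16 by 1.04 ± 0.23, while Serpina6, which encodes the corticosteroid carrier of plasma, rose by 1.78 ± 0.31. The list's mean of -0.37 became -0.23 without knockout 2. The camera adjusted p was 0.0052 (adjusted p = 0.538 with an estimated correlation) and the exact permutation p 0.143. Of 20 serine synthesis and ATF4 genes 2 fell and 1 rose, or 8 and 1 when adjusted over the list alone. The amino acid transporter gene Slc7a5 fell by 0.83 ± 0.13 and Atf5 rose by 0.98 ± 0.22 (camera adjusted p = 0.0059, adjusted p = 0.538 with an estimated correlation, exact permutation p = 0.171). In the hypoxia list 3 of 12 fell, or 4 when adjusted over the list alone, among them the angiogenic factor Vegfa at -0.70 ± 0.16 and Bnip3 at -0.86 ± 0.19. Slc2a1 was among them as well, and the glycolysis list counted it too. The camera adjusted p of the hypoxia list was 0.0418 (adjusted p = 0.538 with an estimated correlation, exact permutation p = 0.114). It was 0.0721, 0.0712, 0.0903, 0.0551 and 0.158 without wild type 1, wild type 2, knockout 1, knockout 2 and knockout 4, 0.0503 with eBayes without a trend, 0.0763 with the mean of all probe sets of a gene and 0.196 with the replicate block. The hypoxia list thus passed in 10 of 18 alternatives that kept the list test. Among runs without 1 array, Slc7a5 and Serpina6 failed only without wild type 3 (adjusted p = 0.0810 and 0.0741), whereas Sgk1, Zbtb16 and Vegfa passed only without knockout 1 (highest 0.170, 0.163 and 0.20), Atf5 only without wild type 2 (0.148) and Bnip3 only without knockout 3 (0.130). Sgk1, Zbtb16, Vegfa and Bnip3 also lost their calls under median scaling and with eBayes without a trend.

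Over all 31 lists, 12 passed with camera, 6 higher and 6 lower. With an estimated correlation camera passed 0 lists, and 3 had an unadjusted p under 0.05. Fry passed 3, glycerol and triglyceride metabolism, fatty acid oxidation, and p53 targets and apoptosis, each at an adjusted p of 0.0103. The smallest exact permutation p was reached by 5 list scores, and none passed after adjustment over 32 scores (smallest adjusted exact p = 0.183). With 35 splits, no score can pass that adjustment unless many scores reach the smallest p together. Its outcome therefore says little about any single list.

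**Figure D3:**
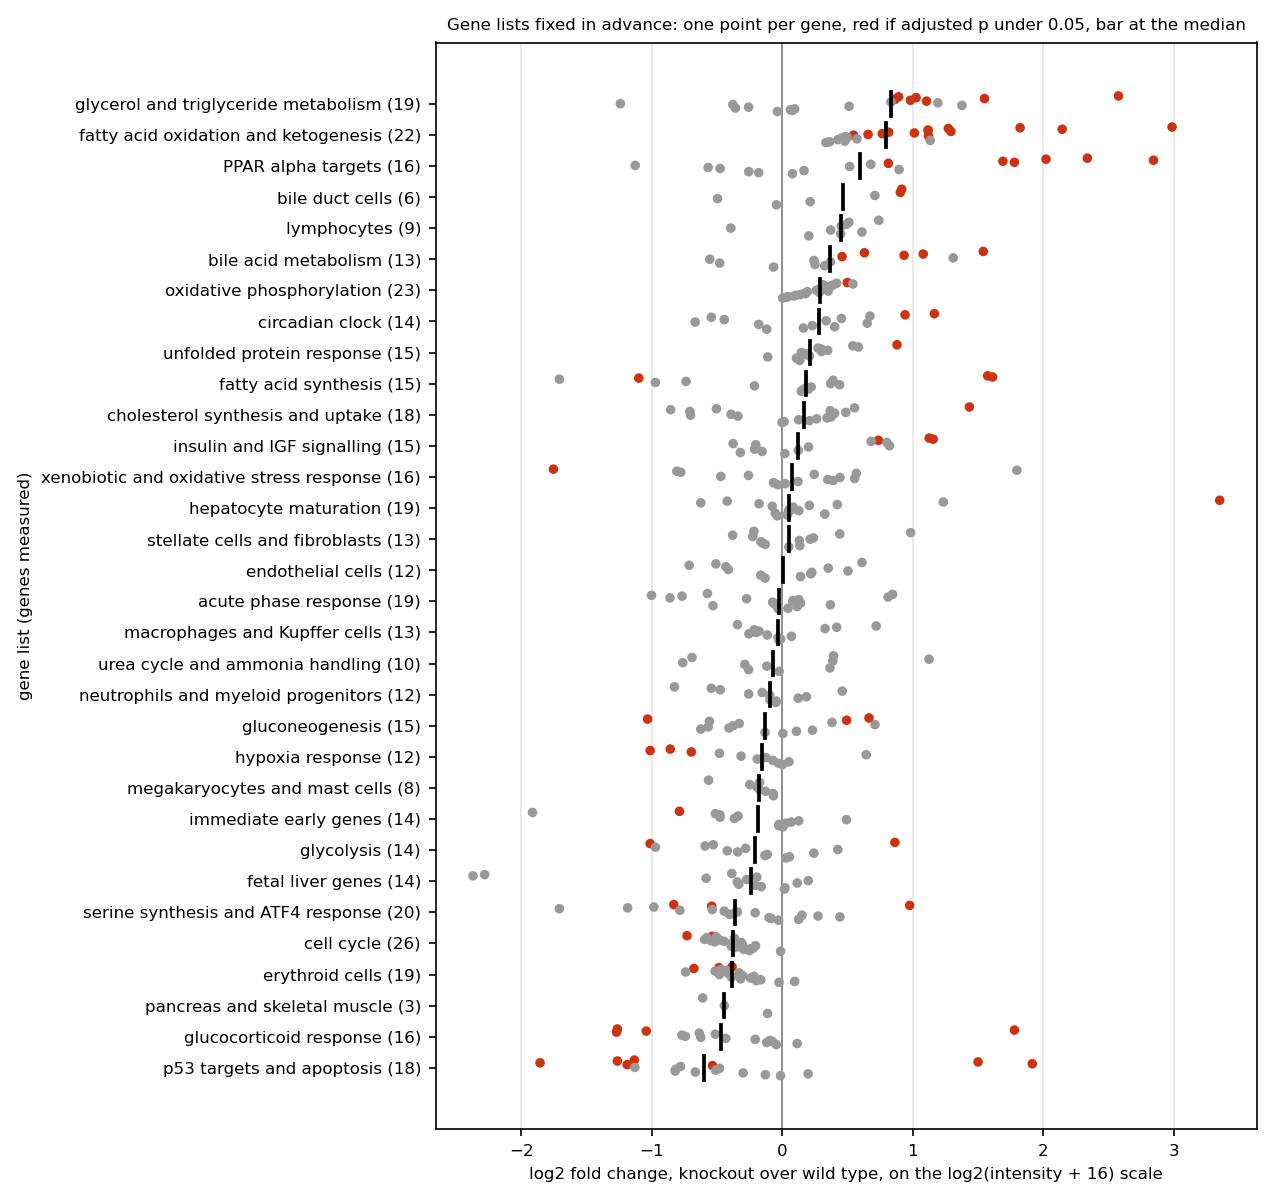
Log2 fold change, knockout over wild type, of each measured gene in the 32 lists, with black bars at list medians and red points for genes past an adjusted p of 0.05. All 22 genes of fatty acid oxidation lie above 0, and all 26 cell cycle genes below it, or 25 under median scaling.

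The other metabolic and signalling lists did not pass, although some of their members did. In fatty acid synthesis (camera adjusted p = 0.72) 2 of 15 genes rose and 1 fell, or 3 and 3 when adjusted over the list alone. Mlxipl, the carbohydrate response factor, rose by 1.57 ± 0.19 and Me1, the malic enzyme, by 1.61 ± 0.21, and both passed whichever array was left out. In insulin and IGF signalling (adjusted p = 0.16) 3 of 15 rose, or 5 when adjusted over the list alone, and Igf1 rose by 1.12 ± 0.17 whichever array was left out. Gluconeogenesis (adjusted p = 0.75) held 2 rises and 1 fall among 15 genes, or 4 and 3 when adjusted over the list alone. Glycolysis (adjusted p = 0.22) held 1 of each among 14, cholesterol synthesis (adjusted p = 0.78) 1 rise among 18, and the circadian clock (adjusted p = 0.27) 2 rises among 14. When adjusted over the list alone the counts were 1 and 1, 1, and 3 rises with 1 fall. The xenobiotic list (adjusted p = 0.99) held 1 fall among 16 and immediate early genes (adjusted p = 0.076) 1 among 14, or 1 rise with 2 falls and 1 fall when adjusted over the list alone. No member passed in the urea cycle (10 genes, adjusted p = 0.98) or the acute phase response (19 genes, adjusted p = 0.75), and adjusted over the list alone the urea cycle held 1 rise and 1 fall and the acute phase response 0. Cholesterol synthesis passed without knockout 1 (adjusted p = 0.0316) and glycolysis without knockout 3 (0.0265). Immediate early genes passed without wild type 2, wild type 3 or knockout 3 (0.0039, 0.0383 and 0.0114), and with no filter (0.0369).

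Markers of other cell types gave no list past the threshold apart from the erythroid one. Hepatocyte maturation genes had a median of 0.05 over 19 genes (camera adjusted p = 0.72), with Cyp1a2 as the only rise, also adjusted over the list alone. Bile duct genes had a median of 0.46 (adjusted p = 0.076), where Krt18 at 0.91 ± 0.14 and Krt8 at 0.90 ± 0.20, keratins that hepatocytes express too, rose among 6 genes, also adjusted over the list alone. Fetal liver genes had a median of -0.24 (adjusted p = 0.082), and the embryonic globin Hbb-y, at -2.28 ± 0.78, did not pass. Its log2 fold change ran from -2.99 to -1.19 under the alternatives. Lymphocyte genes had a median of 0.45 over 9 genes (adjusted p = 0.082), and neutrophil genes one of -0.10 (adjusted p = 0.27). The medians were -0.18 for megakaryocytes and mast cells (adjusted p = 0.17), -0.03 for macrophages (0.91), 0.003 for endothelial cells (0.95) and 0.05 for stellate cells (0.98). Adjusted over the list alone, the endothelial list held 2 rises and 3 falls, and the fetal liver, lymphocyte, neutrophil, megakaryocyte, macrophage and stellate lists 0. Pancreas and skeletal muscle genes, with 3 measured, were not tested and had a median of -0.45, or -0.29 without knockout 1. Bile duct genes passed without knockout 1 or 4 and with the replicate block (adjusted p = 0.0431, 0.0475 and 0.0460), lymphocyte genes without wild type 3 or knockout 3 (0.0167 and 0.0024) and fetal liver genes without wild type 2 or 3 (0.0123 and 0.0310). Neutrophil and megakaryocyte genes passed without wild type 2 (0.0411 and 0.0115). Without wild type 1 the medians were -0.02 for fetal liver genes and 0.03 for megakaryocytes, and without wild type 2 they were -0.36 and -0.36. The neutrophil median was 0.003 without knockout 1 and -0.21 without wild type 2, and the lymphocyte one 0.69 without knockout 3. Leaving out 1 array also took the hepatocyte, macrophage, endothelial and stellate medians to either side of 0, within -0.16 and 0.14. Krt18 did not pass without wild type 3 (0.0614), and among runs without 1 array Krt8 passed only without knockout 1 (highest 0.161).

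Coexpression analysis, named in the title of the series, gave 13 modules of the 4000 most variable probe sets. Module 1 held 2859 of them, 681 of which were called, 401 higher and 280 lower in knockout. Slc25a23, a mitochondrial carrier, and Slco4c1 were among the genes closest to its first component, with correlations of 0.998 and -0.989 across arrays that include both groups. The component of module 1 differed between groups at an exact permutation p of 0.0286, which became 0.371 after adjustment over modules. With 35 splits and 13 modules, 1 module alone could not reach a lower adjusted p. No other module had an unadjusted p under 0.05. No gene list passed a test for enrichment in a module (lowest adjusted p = 0.381). Module 1 held 1971 of the 2686 named genes examined, so that test could hardly show enrichment in it. All 15 fatty acid oxidation genes among the genes examined lay in module 1 (adjusted p = 0.554 in the same test).

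Genes beside the targeted locus on chromosome X were examined because such a locus can carry flanking sequence of another strain. Tmem47 fell by 0.84 ± 0.18 on the log2 scale (adjusted p = 0.0348), while Tab3 at -0.41 ± 0.17 and Dmd, the dystrophin gene, at -0.26 ± 0.22 did not pass. Leaving out any array but knockout 1 ended the call of Tmem47 (highest adjusted p = 0.167), as did median scaling (adjusted p = 0.0581). The median of the 3 genes within 5 Mb, -0.41, lay at percentile 4.07 of 10000 random lists matched on expression.

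Sex-linked transcripts matched the male label in every array. Eif2s3y, on the Y chromosome, had an intensity between 1226 and 1684 by its brightest probe set, and the brightest probe set of Xist, which female cells express from the inactive X, did not exceed 107.9.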

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

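Apart from the count of modules over other splits, which was planned, the tests of explanations in this part were chosen after the results were seen. Of 110 measures over the 4 knockout arrays, 12 had 1 array far from the other 3 by Dixon's test, where chance gives about 1 in 20, or 5.5; the measures are not independent of each other. The gap as a share of the range was 0.905 for Mettl7b, whose log2 level in knockout 3 was 11.46 against 8.55 to 8.83 in the others. It was 0.911 for Gpd1, at 11.70 in knockout 2 against 11.10 to 11.16, so all 4 arrays stayed far above wild type. Dbp had a gap of 0.890 with a low value of 7.22 in knockout 3, and Sel1l one of 0.837 with a low value of 11.39 in knockout 1. Among list scores, PPAR alpha targets were high in knockout 4 (gap 0.847), cell cycle genes low in knockout 1 (0.925) and erythroid genes high in knockout 3 (0.910). Lymphocyte genes were low in knockout 3 (0.855), stellate cell genes high in knockout 2 (0.850), bile acid genes low in knockout 1 (0.879) and glucocorticoid response genes low in knockout 2 (0.835). The transferrin receptor 3' to 5' ratio of 11.1 in knockout 3 had the widest gap, 0.974.

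Higher fatty acid oxidation genes were set against 3 technical explanations. A larger share of hepatocytes would raise hepatocyte genes alike. The 95% bootstrap interval of the maturation list's median, over genes, ended at 0.13, below the lower end of the oxidation list's, 0.52. Resampling genes leaves out the spread between livers. By array, the maturation score was higher by 0.247 in knockout, with SDs of 0.286 in wild type and 0.285 in knockout (exact permutation p = 0.371). The interval therefore cannot settle whether the share of hepatocytes differed. Against the scaling between arrays as the whole cause, the list's mean was 0.967 or more under both other scalings, with a standard error of at most 0.157. Leaving out knockout 3, with its high 3' to 5' ratios, left 0.90 ± 0.09. A biological effect of the knockout stays open as a hypothesis; no batch was used here, and the cre control was lower in every knockout array.

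Lower cell cycle genes had a mean of -0.330 under median scaling and -0.395 under quantile scaling, with a standard error of at most 0.151. This argues only weakly against scaling as the whole cause, because Rrm2 and Cdca8 lost their calls under median scaling. A lower share of erythroid precursors, which divide in newborn liver, may account for the pattern. The cell cycle score changed by -0.038 relative to the erythroid score, well within the SD of 0.187 within groups. Equal mean falls can also arise separately, so this does not show a shared cause. Knockout 1 had the lowest cell cycle score, 10.94, but an erythroid score of 12.33, beside 12.34 in knockout 2 and 12.32 in knockout 4. Knockout 3 had the highest erythroid score of the knockout arrays, 12.55, with a cell cycle score of 11.38. Fewer divisions in other cells stay possible too, because the arrays measure whole liver. Whether the erythroid share also bears on the lower hypoxia, ATF4 and p53 lists was not tested.

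The largest falls were examined for faults of sequence or probes. Flanking sequence of another strain would place them near the targeted gene, but 0 of the 12 genes lay on chromosome X, among 11 with a known chromosome. A fault in single probe sets would spare the other probe sets of a gene. Slco4c1, Fam107a, Esrrg, Trgv4 and Itgae each had 1 other tested probe set, and 100% of these 5 lay below 0 by more than 2 standard errors, 3 of them past the threshold, which argues against such a fault there. The remaining 7 genes had 0 other tested probe sets, so a fault in their single probe sets stays open, although 4 dimmer ones of Rasd2, Minar1 and Gdf3, below the expression filter, were lower too, at -1.36 to -2.89.

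Regrouping of the arrays was applied to each kind of count. Of the 35 splits only the real one, 1 in all, gave as many as 955 probe sets, and the highest other split gave 55. That is the strongest result this regrouping can give (exact permutation p = 0.0286). It argues against chance for that count without excluding it. As many as the 12 lists past camera's threshold were found in 8 of the 35 splits, with a highest other count of 17, so chance cannot be excluded for the number of lists. Modules at an unadjusted p under 0.05 numbered 1 or more in 11 of the 35 splits, with a highest other count of 2. Each of the 13 modules can fall under 0.05 only in its most extreme split, so their number largely sets this spread. The count of modules therefore cannot decide on chance for module 1, which is not excluded.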

How the results depend on the processing

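All alternatives were fixed before the data were examined, and among the 12 lists past the threshold and the called genes chosen by the naming rule none reversed its direction under those run for it. The means of 8 lists that did not pass, and the gene Ppbp, changed sign under some. Array weights gave -0.061 for fatty acid synthesis, -0.053 for the urea cycle, 0.0088 for endothelial cells and -0.043 for the xenobiotic list. The mean of all probe sets of a gene gave -0.018 for the urea cycle, -0.00061 for macrophages and -0.0012 for the xenobiotic list, the 75th percentile filter -0.085 for the xenobiotic list, median scaling 0.034 for endothelial cells and the replicate block -0.056 for macrophages. Without 1 array the means ran from -0.056 to 0.117 for fatty acid synthesis, -0.148 to 0.308 for cholesterol synthesis, -0.031 to 0.076 for the urea cycle, -0.070 to 0.091 for macrophages, -0.367 to 0.0031 for megakaryocytes, -0.092 to 0.056 for endothelial cells, -0.087 to 0.179 for stellate cells and -0.053 to 0.063 for the xenobiotic list, and Ppbp from -0.323 to 0.0093. The cause of these changes of sign was not tested. Against 955 probe sets, 529 higher and 426 lower, eBayes without a trend gave 584, 333 and 251, array weights 2413, 1164 and 1249, no filter 473, 290 and 183, and an adjusted p under 0.1 gave 2032, 999 and 1033. Median scaling gave 218 lower. Without 1 array the count ran from 127 (without wild type 3) to 1006 (without knockout 1), with 105 to 592 higher and 22 to 414 lower; fewer arrays give less power, but why wild type 3 weighed most was not tested. The other alternatives stayed within 1.5 times of each count. Against 12 lists, camera with an estimated correlation gave 0 and fry 3, and leaving out 1 array gave 11 to 15. Against 1 module, a signed network gave 2. The cause of these differences was not tested, except that more probe sets enter the adjustment without the filter. With the replicate block, numbers 1 to 3 as pairs and knockout 4 left out, 352 probe sets passed, 210 higher and 142 lower, and 12 lists. Deviations of same-numbered arrays correlated at 0.0866, -0.0562 and 0.0553. Wild type 1 and wild type 3 correlated best with the knockout array of their own number, and wild type 2 with knockout 3, at 0.119. Correlations this small cannot show whether the numbers mark pairs. The block gave a median of -0.32 for the genes near the targeted gene, and window and scaling changes kept it below 0. The transcript of the targeted gene was not run under any setting. Dim signals limit the results too, since over 35% of probe sets lay under an intensity of 50.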

Other observations

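Gene families by shared symbol stem, 176 in all, were tested with camera after the data had been seen. Acyl-CoA thioesterases were mostly higher in knockout, 9 of 11 measured genes, with 6 past the threshold and a median log2 fold change of 0.75 (adjusted p = 0.00036, adjusted p = 0.732 with an estimated correlation). Signals of Acot1, Acot3 and Acot4 may not be separate, as stated above, so these counts may overstate the number of genes changed. Beside Acot1, Acot2, Acot3 and Acot4, the peroxisomal Acot8 rose by 0.75 ± 0.18 and the mitochondrial Acot13 by 0.88 ± 0.21, but Acot8 passed only without knockout 3 among runs that left out 1 array (highest adjusted p = 0.140), and Acot13 failed without any wild type array or knockout 2 or 4 (0.168). Genes with the Cdkn stem, mostly inhibitors of cyclin-dependent kinases, were lower in all 8 measured members, or in 7 when arrays were scaled to equal medians or wild type 1 was left out (adjusted p = 0.0163, adjusted p = 0.880 with an estimated correlation), and Cdkn3 fell by 1.11 ± 0.15 and Cdkn2d by 0.56 ± 0.13. Cdkn3 failed without wild type 3 (adjusted p = 0.0501) and, among runs without 1 array, Cdkn2d passed only without knockout 3 (highest 0.186). Cdkn2d also failed under median scaling (adjusted p = 0.104). No other family passed. The adjusted p was between 0.058 and 0.066 for 7 more, of which the stems Aldh, Pex, Hsd and Mrpl had a median above 0 and Rbm, Eif and Mcm one below 0. Calls in them numbered 2, 2, 4, 1, 1, 2 and 0. Of the aldehyde dehydrogenases, Aldh3a2, which oxidises fatty aldehydes, rose by 1.91 ± 0.17 and Aldh4a1 by 0.89 ± 0.18. Of the peroxins, which build peroxisomes, 12 of 13 were higher, or 10 to 12 without 1 array. Their median of 0.41 became 0.17 without wild type 1. Pex5 rose by 0.76 ± 0.17 and Pex13 by 0.74 ± 0.17. Aldh3a2 passed whichever array was left out, whereas Aldh4a1 failed without any wild type array or knockout 2 or 4 (highest adjusted p = 0.126), and, among runs without 1 array, Pex5 and Pex13 passed only without knockout 2 and knockout 3, respectively (highest 0.170 and 0.117). The medians of these 9 families kept their sign under both other scalings.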
